A study of Mus musculus with 32 samples.

How the data were processed

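The 32 libraries were made by CEL-seq2 from total RNA of cells sorted into Trizol and sequenced on a NextSeq500 with 75 bp paired ends, per the labels' protocols. Reads were aligned with BWA 0.6.2-r126 to mm10, per the submitters' processing notes. The counter, the annotation and the use of molecular identifiers are not given in the sources used here. The deposited files hold counts per gene symbol, 1 file per library, and no deposited count departed from a whole number. A gene not listed in a file was taken as a count of 0. In all 19974 gene names occurred, 9883 of them in every library, and 10511 to 15649 were detected per library. Names were matched to GENCODE M21 (GRCm38, the same assembly as mm10) for coordinates, given from 1 and as whole genes, with a unique match for 19024. The genes with coordinates in the results are protein-coding. No mitochondrial gene was listed, and 14 spike-in names were left out of totals and tests.

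The libraries fell into 11 sets with identical gene lists, called source tables, which stand for a batch in the files. The first held the 5 unpassaged libraries and replicate 1 of early organoids with Fgf10 and with Fgf1, and the next the other 10 early libraries. Anagen follicles, mixed follicles and each sorted epidermis library had their own, and late organoids were spread over 4. Replicate files differed by more than sampling noise in every pair (chi-square per degree of freedom 3.47 to 69.5, Spearman correlation 0.771 to 0.968), so each counts as 1 replicate. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The group of sorted epidermis was selected for Itga6 and Ly6a, and these genes are no finding between it and other groups.

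Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, which is the source of the adjusted p of each gene. Sorted epidermis, both follicle groups and early and late organoids with forskolin and Fgf1 were fitted together (17 libraries, 10843 genes), the passaged organoid groups together (18 libraries, 9919 genes), and early against unpassaged organoids with medium as a term (16 libraries, 9116 genes). The unpassaged library with forskolin alone had no passaged partner and entered no comparison. CPM are TMM-scaled within each fit, so a group's mean differs slightly between fits. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group's summed total. Floors cover counting error only. At the filter's minimum count of 10, counting error alone spans several fold, and genes near it were read as uncertain.

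In all 37 lists (570 genes) of cell types, layers and pathways were tested with camera from limma 3.58.1 with a preset correlation of 0.01, where at least 3 genes passed the filter. The adjusted p of a list is camera's, over the lists of a comparison. Of 274 list tests 86 passed, and 9 held with an estimated correlation. These were hair matrix and inner root sheath for epidermis against anagen follicles; outer root sheath, upper follicle, fibroblast, antigen presentation and red blood cell genes for the follicle pair; NRF2 targets and antigen presentation for late organoids against epidermis; and the p53 and senescence list for passaging. The groups, lists, tests, designs and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 8 largest changes each way among genes past the test with at least the median expression and no overlap between groups, leaving out predicted genes and pseudogenes, up to 4 genes per described list, and Krt5, Krt14, Itga6, Ly6a, Krt10, Lor, Mki67, Cd34 and Lgr5 throughout. Some of the first kinds were left out for length. The result of 1 gene that the rule names is not reported here. Lgr5 fell under the filter in comparisons among organoids. The tissue score used genes past the test with an absolute log2 fold change over 1, log2 CPM with a prior count of 2, and exact permutation tests, with 100 genes per side as an alternative.

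On simulated counts with 200 changed genes, the test called 8% of genes changed 4-fold for epidermis against anagen follicles (9908 genes), 22% for the follicle pair (9980), 48% and 49% for late organoids against epidermis (10030) and anagen follicles (10019), 37% for late against early (9502), 39% for Fgf1 against Fgf10 (9488), 63% for the inhibitor against Fgf10 (9530), 23% for forskolin (9561) and 88% for passaging (8909). Of genes changed 2-fold it called 50% for passaging and 3% or fewer elsewhere, and 10 or fewer unchanged genes were called. Only these 200 genes changed in the simulation, so its adjusted cutoff was stricter than in comparisons where many genes changed. For epidermis against anagen follicles it called 8 genes in all, against 3711 in the real data. The shares are therefore not those of the real tests.

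Alternatives were DESeq2 1.42.0, other scalings, other count filters, smaller fits, thinning to equal depth, each library left out in turn, replicate number as a block and source table as a term. Chosen after seeing the data were the restriction to genes listed in every file, mixed in place of anagen follicles, early in place of late organoids, fits without late libraries or without late replicates 1 and 2, and fits without pseudogene copies. Genes of near-identical families (Krt6a, Krt6b, Krt16 and Krt17, the Sprr2, Lce and Krtap genes, and genes with processed pseudogenes such as Gapdh) can share reads, and their values are uncertain. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.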

Results

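Gene expression was measured by CEL-seq2, a method that counts the 3′ ends of polyadenylated transcripts, in 32 libraries of mouse epidermis (strain Bl/6). Organoids are clusters of keratinocytes grown in 3 dimensions, here from skin, and were harvested after 7 days of culture or 7 days after the last passage. The media held forskolin, which raises cyclic AMP, with the growth factor Fgf10 or Fgf1 or with an inhibitor of TGF-beta signalling, or held forskolin or the inhibitor alone. Unpassaged organoids gave 1 library for each of 5 media. Early organoids (passages 7 to 12, within 3 months) gave 4 libraries with forskolin and Fgf10, 2 with forskolin and Fgf1, 4 with forskolin and the inhibitor, and 2 with the inhibitor alone. Late organoids (passages 23 to 30, within 6 months) gave 6 libraries with forskolin and Fgf1. Tissue gave 3 libraries of anagen hair follicles, 3 of a mixture of anagen and telogen follicles, and 3 of interfollicular epidermis sorted for Itga6 and Sca1 (gene Ly6a). Total counts ranged from 412582 to 3351435 per library (median 1505354), with 469839 to 739531 in sorted epidermis, 1520797 to 2057589 in anagen follicles, 1385192 to 3351435 in mixed follicles and 412582 to 3127190 in late organoids. Among early organoids they were 1489911 to 1994447 with Fgf10, 2435090 to 2562017 with Fgf1, 734041 to 2337596 with forskolin and the inhibitor, and 1101376 to 1206362 with the inhibitor alone. The unpassaged libraries held 1633941 counts with forskolin, 1375714 with added Fgf10, 1028720 with added Fgf1, 2076360 with added inhibitor and 2226115 with the inhibitor alone.

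The first comparison set sorted interfollicular epidermis against anagen hair follicles. Genes of the growing hair were low or at 0 in the epidermis. Krt25, an inner root sheath keratin (chromosome 11, 99315516 to 99322951), had 18420 ± 3745 CPM in follicles (SD, n = 3) and no count in the 3 epidermis libraries, at least 14070-fold lower. Krt71, its type II partner (chromosome 15, 101733949 to 101743109), was at least 11150-fold lower, from 14590 ± 3149 CPM. Of 17 measured genes of hair matrix and inner root sheath, 16 were lower in epidermis and 1 did not pass the test (16 adjusted over the list alone). Their median log2 fold change was -11.94, or -8.02 with genes at 0 set to their bound (adjusted p = 2.42e-23, and adjusted p = 0.0325 with an estimated correlation). All 22 measured hair shaft genes were lower (22 adjusted over the list alone, median -13.71, or -11.28 with bounds, adjusted p = 0.0581 with an estimated correlation), among them Krt35 at 0.352 ± 0.610 against 619 ± 211 CPM. Targets of BMP signalling were lower in 6 of 8 cases (6 adjusted over the list alone, median -3.51, or -2.62 with bounds, adjusted p = 0.0581 with an estimated correlation). Msx2, a transcription factor of the hair matrix, had 15.5 ± 2.65 against 692 ± 393 CPM. Of 20 cholesterol synthesis genes 15 were lower (15 adjusted over the list alone, median -2.26, adjusted p = 0.230 with an estimated correlation), including Sqle, which encodes squalene epoxidase, at 5.57 ± 4.15 against 156 ± 48.4 CPM. All 6 measured melanocyte genes were lower (6 adjusted over the list alone, median -6.56, or -3.33 with bounds, adjusted p = 0.0942 with an estimated correlation).

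Genes of the basal layer were higher in sorted epidermis. The cells were sorted for Itga6, a gene of the basal list, so sort and tissue cannot be told apart for these genes. Of 16 basal keratinocyte genes 11 were higher and 5 did not pass (11 higher and 1 lower adjusted over the list alone, median 2.88, adjusted p = 0.0943 with an estimated correlation). Col17a1, a hemidesmosome collagen (chromosome 19, 47646344 to 47692094), had 2405 ± 692 against 51.1 ± 37.8 CPM. Krt5 had 7577 ± 1599 against 654 ± 413 CPM (log2 fold change 3.53, SE 0.61, adjusted p = 0.000333) and Krt14, its partner, 5655 ± 658 against 365 ± 143. Krt15, a keratin of basal and bulge cells, had 7751 ± 438 against 102 ± 79.1 CPM (log2 fold change 6.24). Of 12 interferon response genes 9 were higher (9 adjusted over the list alone, median 3.45, adjusted p = 0.0581 with an estimated correlation), among them Irf9 at 86.01 ± 11.35 against 5.76 ± 2.05 CPM and Psmb8 of the immunoproteasome. H2-Aa and Cd74, class II antigen presentation genes that mark Langerhans cells in epidermis, had 127 ± 59.3 against 2.34 ± 1.55 and 34.9 ± 8.64 against 0.403 ± 0.698 CPM, and 5 genes of that list were higher and 1 lower of 7 (5 and 1 adjusted over the list alone, adjusted p = 0.0581 with an estimated correlation). Ngfr, a neurotrophin receptor, was at least 92.4-fold higher, from 52.7 ± 6.75 CPM against 0. Lgr5, a follicle stem cell receptor, was lower at 0.470 ± 0.814 against 30.99 ± 27.21 CPM (log2 fold change -5.91, adjusted p = 0.00636), and Mki67, a proliferation gene, at 37.0 ± 12.9 against 169 ± 118. Krt10, Lor and Cd34 did not pass (Krt10 1166 ± 161 against 68.0 ± 47.4 CPM, adjusted p = 0.0859). Itga6 and Ly6a were higher too, but the sort selected for them. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3711 of 10843 genes differed, 1609 higher and 2102 lower in epidermis, a share of 43.4% higher that was 54.1% with upper quartile scaling. The median of all genes was -0.15 here and 0.09 with that scaling. Against the mixed follicles Krt5 (log2 fold change -0.12, adjusted p = 0.902) and Krt14 (-0.22, adjusted p = 0.816) did not differ by the test. Col17a1 (3.44) did, as did Itga6 (3.99), for which the cells were sorted. The antigen presentation list did not pass (median 0.91, adjusted p = 0.427). The epidermis and follicle libraries lay in different source tables. Krt25 and Krt35 followed tissue over all 5 of them. They were at 7292 to 20440 and 371 to 946 CPM in every library of both follicle tables. In the 3 epidermis tables they were at 0 and at most 1.10 (scaled over all 32 libraries). No table held both tissues, so tissue and table cannot be told apart by the design, for these or for genes with smaller differences.

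Anagen follicles were compared with the mixture of anagen and telogen follicles. The anagen preparation had less of the genes of the outer root sheath list. This sheath is the epithelial layer continuous with the basal epidermis, and the list includes Krt5, a basal keratin of both. Krt5 and Krt14 did not differ by the test between sorted epidermis and mixed follicles, so they do not separate sheath from interfollicular epidermis. Of 7 measured outer root sheath genes 5 were lower (6 adjusted over the list alone, median log2 fold change -3.65, adjusted p = 0.0419 with an estimated correlation), among them Krt5 at 654 ± 413 against 8212 ± 2579 CPM (n = 3 each), Krt17 at 75.3 ± 12.1 against 549 ± 314 and the transcription factor Barx2. Of 9 genes of the upper follicle and junctional zone 3 were lower (6 adjusted over the list alone, median -4.34, or -3.13 with bounds, adjusted p = 0.0380 with an estimated correlation): the keratin Krt79, the BMP and Wnt antagonist Sostdc1 and the defensin Defb6 at 25.1 ± 8.10 against 1032 ± 430 CPM. Krt14 was lower at 365 ± 143 against 6592 ± 1929 CPM, and Ly6a at 4.46 ± 3.85 against 260 ± 96.4.

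Genes of other skin cells were also lower in anagen than in mixed follicles. Of 9 fibroblast genes 7 were lower (7 adjusted over the list alone, median -4.59, adjusted p = 0.0325 with an estimated correlation), among them Sparc, a matrix glycoprotein, at 44.0 ± 26.1 against 1071 ± 283 CPM and the collagens Col1a2 and Col3a1. Class II antigen presentation genes were lower in 3 of 7 cases (4 adjusted over the list alone, median -4.03, adjusted p = 0.0325 with an estimated correlation), with H2-Aa at 2.34 ± 1.55 against 68.97 ± 31.01 CPM. All 3 measured red blood cell genes were lower (3 adjusted over the list alone, median -7.36, adjusted p = 0.0325 with an estimated correlation), including the haemoglobin gene Hba-a1 at 0.134 ± 0.233 against 44.1 ± 22.7 CPM. Higher in anagen follicles were Hells (31.2 ± 18.9 against 5.58 ± 4.96 CPM) and Pola1 of the 25 DNA replication genes (2 higher, 6 adjusted over the list alone, median 1.23, adjusted p = 0.728 with an estimated correlation), and Krt72 of the inner root sheath at 75.3 ± 51.9 against 12.4 ± 3.74. Mki67 (169 ± 118 against 38.5 ± 19.9 CPM), Krt10, Lor, Itga6, Cd34 and Lgr5 did not pass. Gapdh, a glycolytic enzyme with many pseudogene copies (chromosome 6, 125161715 to 125166467), had 2.65 ± 1.67 against 4263 ± 932 CPM (log2 fold change -10.55, adjusted p = 8.58e-07), and Vmn2r55, a vomeronasal receptor gene, 3231 ± 880 against 13.3 ± 5.38. By the same edgeR test 719 genes differed, 131 higher and 588 lower in anagen follicles. With libraries thinned to equal depth 362 genes differed, and single libraries counted: 400 without anagen replicate 2, 439 without mixed replicate 2 and 458 without mixed replicate 3. Each preparation filled a source table of its own.

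Late organoids grown with forskolin and Fgf1 were compared with sorted epidermis to ask how close long-term cultures stayed to these sorted cells. The epidermis held only cells sorted for Itga6 and Sca1, while organoids were bulk cells. For genes of basal and differentiated layers, including the cornified envelope, the sort and culture therefore cannot be told apart. The basal keratins did not pass the test: Krt5 had 10710 ± 3658 (n = 6) against 7577 ± 1599 CPM (n = 3, log2 fold change 0.50, SE 0.49, adjusted p = 0.511) and Krt14 8386 ± 4891 against 5655 ± 658 (adjusted p = 0.481). Genes of wounded or cultured keratinocytes were higher in organoids. Of 19 such genes 15 rose (16 adjusted over the list alone, median log2 fold change 6.31, adjusted p = 0.163 with an estimated correlation), among them the alarmin S100a9 at 1194 ± 1158 against 2.40 ± 2.91 CPM, the cytokine Il1a and the EGF receptor ligand Hbegf at 56.4 ± 41.8 against 2.58 ± 1.01. The outer root sheath and wound keratins Krt6a (3560 ± 2803 against 44.8 ± 69.9 CPM) and Krt17 (1033 ± 494 against 217 ± 91.7) rose with 3 others of 7 in their list (5 adjusted over the list alone, median 2.50, adjusted p = 0.197 with an estimated correlation). Of 24 cornified envelope genes 18 rose and 1 fell (18 and 1 adjusted over the list alone, median 5.65, or 5.01 with bounds, adjusted p = 0.695 with an estimated correlation). Sprr1a had 759 ± 628 against 7.68 ± 5.56 CPM, and Alox12e was the 1 that fell. With replicate number as a block, a fit that rests on late replicates 1 to 3, the test of this list against other genes turned to lower in late organoids. The median of the list stayed positive in that fit.

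Metabolic genes were higher in late organoids than in epidermis. Of 20 genes of glucose use and hypoxia 15 rose (18 adjusted over the list alone, median 3.71, adjusted p = 0.163 with an estimated correlation), including Pgk1, a glycolytic enzyme, at 3180 ± 1467 against 151 ± 7.41 CPM and Ldha at 1064 ± 454 against 111 ± 18.9. Of 20 cholesterol synthesis genes 18 rose (18 adjusted over the list alone, median 3.14, adjusted p = 0.109 with an estimated correlation), including Sqle at 89.8 ± 29.7 against 5.57 ± 4.15 CPM. Of 16 targets of NRF2, the regulator of the oxidative stress response, 11 rose and 1 fell (12 and 1 adjusted over the list alone, median 2.78, adjusted p = 8.15e-06, and adjusted p = 0.0413 with an estimated correlation), among them the cystine transporter Slc7a11 and Gsta4 at 2444 ± 2222 against 22.4 ± 32.0 CPM. Mitotic genes rose in 13 of 26 cases (21 adjusted over the list alone, median 2.34, adjusted p = 0.553 with an estimated correlation), with Ube2c at 150 ± 108 against 10.6 ± 5.46 CPM, whereas Mki67 did not pass at 53.2 ± 42.5 against 37.0 ± 12.9. Of 25 DNA replication genes 1 rose and 5 fell (1 and 7 adjusted over the list alone, median -0.81, adjusted p = 0.695 with an estimated correlation), with Rrm2 higher and the helicase gene Mcm2 lower, at 40.6 ± 16.9 against 109 ± 10.1 CPM. Cdkn2b rose to 77.98 ± 44.89 from 4.81 ± 3.16 CPM. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19ARF (chromosome 4, 89274471 to 89294653), had 18.1 ± 8.82 CPM against 0, at least 13.9-fold higher. Pitx1, a homeobox gene of hindlimb and oral development (chromosome 13, 55825051 to 55836192), was at least 351-fold higher, at 460 ± 264 CPM against 0 counts.

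Lower in late organoids were Apoe, Krt15, some hemidesmosome genes and genes of immune cells. Apoe, a lipid transport gene (chromosome 7, 19696109 to 19699188), fell from 11350 ± 2098 to 8.33 ± 3.38 CPM (log2 fold change -10.34, SE 0.51, adjusted p = 6.97e-10). Krt15 fell from 7751 ± 438 to 208 ± 263 CPM, and the hemidesmosome genes Dst (1159 ± 118 to 106 ± 58.5) and Col17a1 (2405 ± 692 to 818 ± 389) fell, while the integrin gene Itgb1 rose. Class II antigen presentation genes fell in 5 of 7 cases and 1 rose (5 and 1 adjusted over the list alone, median -5.78, or -3.91 with bounds, adjusted p = 1.00e-05, and adjusted p = 0.0413 with an estimated correlation), with H2-Aa at 0.241 ± 0.590 against 127 ± 59.3 CPM. The 1 that rose was Mfge8, a secreted glycoprotein gene. Of 12 interferon response genes 7 fell and 1 rose (8 and 1 adjusted over the list alone, median -1.94, adjusted p = 0.0650 with an estimated correlation), among them Tap1 at 7.74 ± 3.17 against 112 ± 19.0 CPM. Lor, a cornified envelope protein gene (chromosome 3, 92080271 to 92083142), had 1538 ± 2208 against 50.5 ± 8.80 CPM (adjusted p = 0.0499), and Krt10 1919 ± 2627 against 1166 ± 161 (adjusted p = 0.765). Late replicates 1 to 3 had only 7, 1 and 82 Krt10 counts, and 5.96 to 15.1 CPM of Lor, below every epidermis library at 43.9 to 61.7 (scaled over all 32 libraries). The Lor call was lost without epidermis replicate 1, 2 or 3 (adjusted p = 0.140, 0.158 and 0.140), without late replicate 4, 5 or 6 (adjusted p = 0.0748, 0.0605 and 0.0689) and with RLE or upper quartile scaling (adjusted p = 0.0502 and 0.0527). With replicate number as a block, a fit that rests on late replicates 1 to 3, Lor and Krt10 turned lower in late organoids. Itga6 (152 ± 106 against 298 ± 62.1 CPM), Ly6a (557 ± 277 against 222 ± 50), which the sort selected for, and Cd34 did not pass. Lgr5 had no count in late organoids. By edgeR 2360 genes differed, 1327 higher and 1033 lower. A fit of these groups alone called 1377, and 1406, 1296 and 1528 were called without sorted epidermis replicate 1, 2 and 3. Organoid and tissue libraries shared no source table.

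Late organoids were also compared with anagen follicles, to place the cultures against hair as well as epidermis. Hair genes were lower in organoids, and basal keratins were higher than in anagen but not in mixed follicles. Of 22 hair shaft genes 21 were lower (21 adjusted over the list alone, median log2 fold change -14.31, or -12.62 with bounds, adjusted p = 0.0936 with an estimated correlation), and 16 of 17 hair matrix and inner root sheath genes (16 adjusted over the list alone, median -9.76, or -7.58 with bounds, adjusted p = 0.0519 with an estimated correlation). Krt25 was at least 46840-fold lower, and Tchh, trichohyalin of the inner root sheath, had 3.24 ± 2.19 (n = 6) against 9629 ± 4482 CPM (n = 3). Basal genes were higher in 11 of 16 cases (12 higher and 1 lower adjusted over the list alone, median 2.89, adjusted p = 0.225 with an estimated correlation), with Krt5 at 10710 ± 3658 against 654 ± 413 CPM (adjusted p = 4.41e-05) and Lama3, a laminin gene, at 175 ± 98.4 against 13.8 ± 4.57. Genes of wounded keratinocytes were higher in 17 of 19 cases (17 adjusted over the list alone, median 5.61, or 5.42 with bounds, adjusted p = 0.347 with an estimated correlation), including Krt6b at 3594 ± 3635 against 0.134 ± 0.233 CPM. Glucose and hypoxia genes were higher in 16 of 20 cases (16 adjusted over the list alone, median 3.49, adjusted p = 0.380 with an estimated correlation), with the glucose transporter gene Slc2a1 at 191.5 ± 88.04 against 1.88 ± 1.68 CPM. BMP targets were lower in 5 of 8 cases (5 adjusted over the list alone, median -3.22, adjusted p = 0.0938 with an estimated correlation), including Id3 at 23.03 ± 11.01 against 200.1 ± 37.2 CPM. Pitx1 was at least 805-fold higher. Lgr5 was at least 78.8-fold lower, and Itga6 and Ly6a were higher. Mki67 was lower than in anagen follicles (53.2 ± 42.5 against 169 ± 118 CPM) but not lower than in mixed follicles. Krt10 and Lor had higher means (adjusted p = 0.0355 and 0.00471), but late replicates 1 to 3 had 1.99 to 22.5 CPM of Krt10, below the anagen libraries at 31.9 to 121, and 5.96 to 15.1 of Lor against 5.31 to 9.45 (scaled over all 32 libraries). The Krt10 call was lost without any single anagen library (adjusted p = 0.0669, 0.109 and 0.109 without replicates 1, 2 and 3) and without late replicate 4 or 6 (adjusted p = 0.0514 and 0.0581). Cd34 did not pass. By edgeR 4966 genes differed, 2298 higher and 2668 lower. Against mixed follicles Krt5 (log2 fold change 0.38, adjusted p = 0.561), Krt14 (0.35, adjusted p = 0.628), Ly6a (1.10, adjusted p = 0.149), Krt10 (adjusted p = 0.869) and Lor (adjusted p = 0.0530) did not pass, while the basal list did (median 1.80, adjusted p = 0.00594), and Gapdh was lower in place of higher (-4.90 against 5.65). Scaled over all libraries, Gapdh averaged 4326 CPM in mixed follicles and 2.60 to 148 in the other 12 groups. Thinned libraries gave 3305 genes.

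A tissue score, the mean log2 CPM of 1577 genes higher in sorted epidermis minus that of 2048 genes higher in anagen follicles, placed every library on an axis between those tissues. Sorted epidermis scored 2.32 ± 0.05 and anagen follicles -2.92 ± 0.58 by construction (SD, n = 3 each), and mixed follicles -1.81 ± 0.31. Mixed follicles and passaged organoids with Fgf1 were outside the contrast that chose the genes. They were in its fit, however, and so shaped its filter, scaling and estimate of spread. Late organoids scored 0.78 ± 0.21 (n = 6), above both early libraries with the same medium (0.23 ± 0.07, n = 2). The difference of 0.55 had an exact two-sided permutation p = 0.0357, the smallest that 28 arrangements allow (adjusted p = 0.143 over 4 comparisons). Late and early libraries shared no source table, so culture age and table cannot be told apart in this score. Late organoid and sorted epidermis files listed 12166 to 13590 genes. Early organoid and follicle files listed 14946 to 17360, and unlisted genes were taken as 0. Whether this moved late organoids along the axis was not tested. Early organoids scored 0.25 ± 0.11 with Fgf10 (n = 4), 0.28 ± 0.06 with forskolin and the inhibitor (n = 4) and 0.27 ± 0.01 with the inhibitor alone (n = 2), and no difference between these media passed (exact permutation p = 0.657 for the inhibitor against Fgf10, 0.933 for Fgf1 against Fgf10 and 0.733 for forskolin, where the last 2 cannot go below 0.0667). With 100 genes per side in the score these differences were larger or turned, at 0.18 (exact permutation p = 0.0571) in place of 0.03, -0.17 in place of -0.02 and -0.06 in place of 0.02, and that of late minus early was 0.65. Unpassaged organoids scored from 0.22 to 0.53. Across genes, each of the 23 organoid libraries had a higher Spearman correlation with sorted epidermis (0.755 to 0.812) than with anagen (0.627 to 0.737) or mixed follicles (0.610 to 0.744), where genes are not independent replicates. Late organoids had lower mean Spearman correlations than early ones with the same medium, at 0.772 ± 0.0184 against 0.792 ± 0.000424 with sorted epidermis and 0.663 ± 0.0321 against 0.720 ± 0.00226 with anagen follicles, and these differences were not tested.

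**Figure D1:**
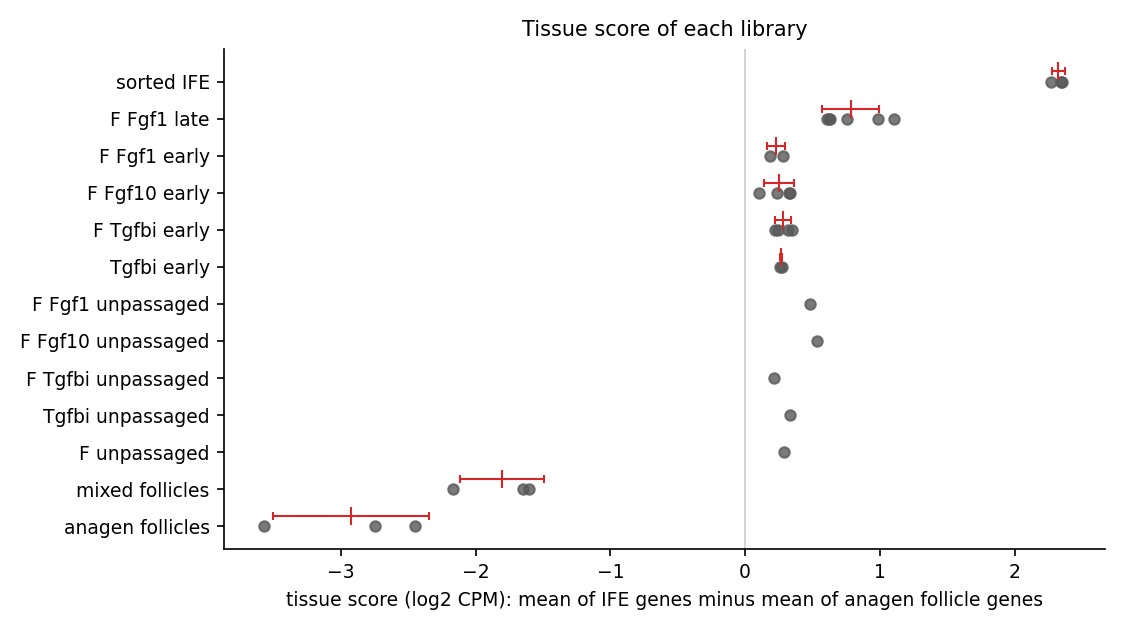
Tissue score (log2 CPM) of each library on the horizontal axis, by group on the vertical axis, with points for libraries and red bars for the group mean ± SD. Late organoids lie between 0.60 and 1.10, to the right of every early library and left of sorted epidermis at 2.32.

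The effect of long culture was taken from late against early organoids with forskolin and Fgf1. Krt16, Sprr1b, Ccl20 and Tslp, genes of activated keratinocytes, were among those lower in late organoids, with calls that depended on the early pair of libraries. Krt16 (chromosome 11, 100246091 to 100248902), a keratin of wounded epidermis, fell from 14600 ± 894 (n = 2) to 886 ± 939 CPM (n = 6, log2 fold change -4.04, SE 1.05, adjusted p = 0.0281). Sprr1b, a cornified envelope precursor gene, fell from 8513 ± 6480 to 802 ± 791, and the genes of the chemokine Ccl20 and the cytokine Tslp fell to 3.04 ± 2.21 and 13.65 ± 14.98 CPM. Of 19 genes of wounded keratinocytes 3 fell (2 rose and 6 fell adjusted over the list alone, median -1.07, adjusted p = 0.00688, and adjusted p = 0.665 with an estimated correlation). Krt14 fell from 27550 ± 4559 to 9110 ± 5255 CPM (log2 fold change -1.60, adjusted p = 0.0330), while Krt5 did not pass at 16980 ± 4805 and 11690 ± 4070. Thbd, the thrombomodulin gene, fell from 142 ± 82.4 to 5.56 ± 6.35 CPM and Tubb3, a neuronal tubulin gene, from 142 ± 37.1 to 7.62 ± 9.57.

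Higher in late organoids were Ngfr (chromosome 11, 95568818 to 95587735) at 159 ± 159 against 0.811 ± 0.020 CPM (log2 fold change 7.47, adjusted p = 0.00853, and by edgeR 0.106 without early replicate 1 and 0.117 without early replicate 2) and the circadian repressors Bhlhe41 (106 ± 74.1 against 0.804 ± 0.553) and Nr1d1 (209 ± 240 against 13.6 ± 0.628). Id2, an inhibitor of basic helix-loop-helix factors (chromosome 12, 25093799 to 25097140), rose from 10.1 ± 0.892 to 89.01 ± 53.04 CPM, and Txnip, a thioredoxin inhibitor, from 9.42 ± 7.69 to 84.6 ± 43.3. Krt10, a keratin of differentiating suprabasal cells (chromosome 11, 99385254 to 99389364), did not differ by the test, at 2087 ± 2860 and 1724 ± 1726 CPM (adjusted p = 0.945), nor did Lor at 1674 ± 2413 and 1535 ± 496. Late libraries split widely in Krt10, from 1.99 CPM in replicate 2, 10.3 in replicate 1 and 22.5 in replicate 3 to 954 or more in the others. Itga6, Ly6a, Mki67 and Cd34 did not pass either. By edgeR 666 of 9919 genes differed, 297 higher and 369 lower, a share of 44.6% higher that was 59.0% among the 1137 genes DESeq2 called. This count rested on the early libraries: 85 genes were called without early replicate 1, 44 without early replicate 2 and 1 in a fit of these groups alone, against 1097 without late replicate 4. Of the 32 called genes that the naming rule takes, 6 passed without early replicate 1, 5 without early replicate 2 and 0 in the fit of these groups alone, with the sign kept in 32, 32 and the 31 that this fit tested. Thbd and Tubb3 passed without either early library, while Krt16, Krt14, Sprr1b, Ngfr, Bhlhe41, Nr1d1 and Id2 lost the call without each. Late and early libraries shared no source table, so culture age and table cannot be told apart.

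**Figure D2:**
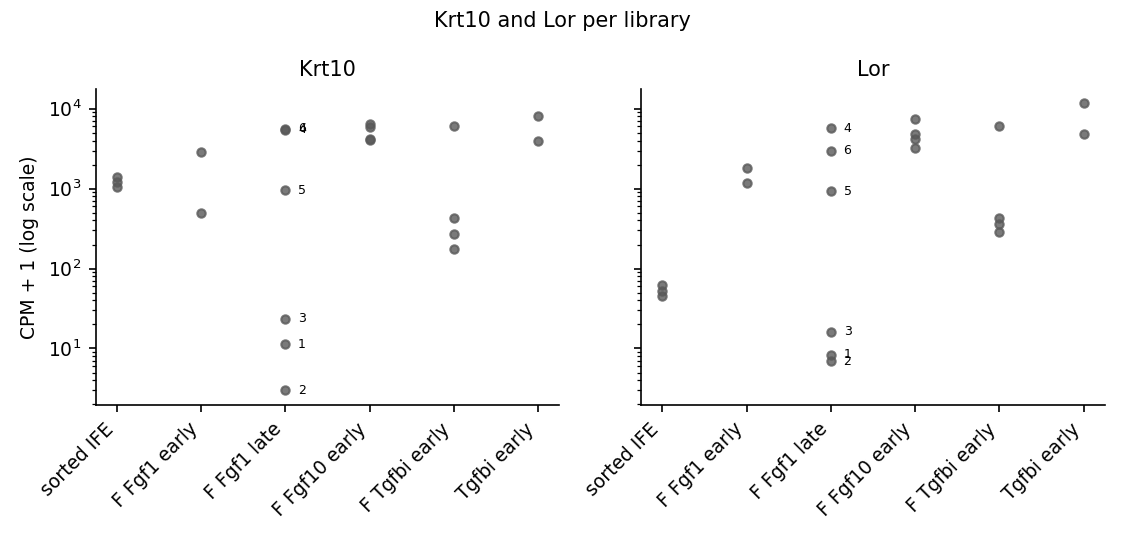
CPM plus 1 on a log axis for Krt10 and Lor in each library of sorted epidermis and passaged organoids, with late libraries numbered by replicate. Krt10 in late replicates 1 to 3 lies at 22.5 CPM or lower and in replicates 4 to 6 at 954 CPM or higher.

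Fgf1 and Fgf10 were compared in early organoids with forskolin. Differentiation genes had lower averages with Fgf1. Krt10 had 1724 ± 1726 (n = 2) against 5327 ± 1238 CPM (n = 4) and Lor 1535 ± 496 against 5131 ± 1910, neither past the test (adjusted p = 1 for each). The basal keratins were at 16980 ± 4805 against 13640 ± 1676 CPM for Krt5 and 27550 ± 4559 against 20870 ± 4056 for Krt14. Cd34, a bulge stem cell gene, had 14.1 ± 3.66 against 0.759 ± 0.533 CPM, also short of the test. None of 25 cornified envelope genes (0 adjusted over the list alone, median -1.31) and none of 26 mitotic genes (0 adjusted over the list alone, median 0.64) passed. As groups they did with a preset correlation (adjusted p = 0.00344 and 0.00117), but not with an estimated one (adjusted p = 0.627 for each list). The edgeR test called 0 genes, with 328 at an unadjusted p under 0.05, fewer than the 496 that chance gives, while DESeq2 called 15. A fit without the late libraries called 23, edgeR called 6 without Fgf10 replicate 4, and a fit of these groups alone called 43. Replicate 1 of each medium lay in 1 source table and the other libraries in another, and with the source table as a term 4 genes were called.

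The TGF-beta inhibitor was compared with Fgf10 in early organoids with forskolin, media that differ in both additions. A gene named for its induction by TGF-beta, Tgfbi, fell from 82.2 ± 27.1 to 15.9 ± 2.62 CPM with the inhibitor (n = 4 each, log2 fold change -2.35, SE 0.37, adjusted p = 0.00641). It was the 1 of 19 TGF-beta targets to pass (3 fell adjusted over the list alone, median -0.83, adjusted p = 1.45e-06, and adjusted p = 0.238 with an estimated correlation). The BMP targets Id2 (71.2 ± 26.3 against 8.74 ± 3.11 CPM) and Id3 (chromosome 4, 136143497 to 136145755; 209 ± 92.4 against 42.6 ± 14.1) rose, 2 of 6 in their list (3 rose and 1 fell adjusted over the list alone, median 0.90, adjusted p = 0.238 with an estimated correlation). Apoe rose from 47.7 ± 24.8 to 696 ± 312 CPM (log2 fold change 3.87, adjusted p = 0.000118). Cyp26b1, which breaks down retinoic acid, rose from 43.0 ± 16.9 to 177 ± 65.6, Odc1 of polyamine synthesis from 38.2 ± 12.1 to 192 ± 105, and the keratin Krt17 from 570 ± 260 to 1978 ± 107.

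Lower with the inhibitor were the homeobox gene Irx4 (chromosome 13, 73260479 to 73269608) at 1.14 ± 1.08 against 48.7 ± 9.12 CPM and Sostdc1 (chromosome 12, 36314139 to 36318452) at 3.06 ± 0.533 against 118 ± 96.8. The matrix genes Sparc (7.24 ± 2.89 against 84.4 ± 74.7 CPM) and Lamb1 and the integrin gene Itgb5 (4.38 ± 1.51 against 53.6 ± 13.6) fell as well. No single mitotic gene of 26 passed (0 adjusted over the list alone), and their median was 0.97 (adjusted p = 1.69e-09, and adjusted p = 0.512 with an estimated correlation). Mki67 had 118 ± 32.3 against 50.3 ± 33.3 CPM (adjusted p = 0.737). Krt5, Krt14 (11490 ± 1555 against 20870 ± 4056 CPM, adjusted p = 0.673), Krt10, Lor, Itga6, Ly6a and Cd34 did not pass. By edgeR 57 genes differed, 26 higher and 31 lower, and 103 with source table as a term. Thinned libraries gave 8 genes, 17 were called without inhibitor replicate 3, 21 and 33 without replicates 2 and 1, and 23 and 30 without Fgf10 replicates 1 and 2. The call of Id3 was lost without each of 6 single libraries.

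**Figure D3:**
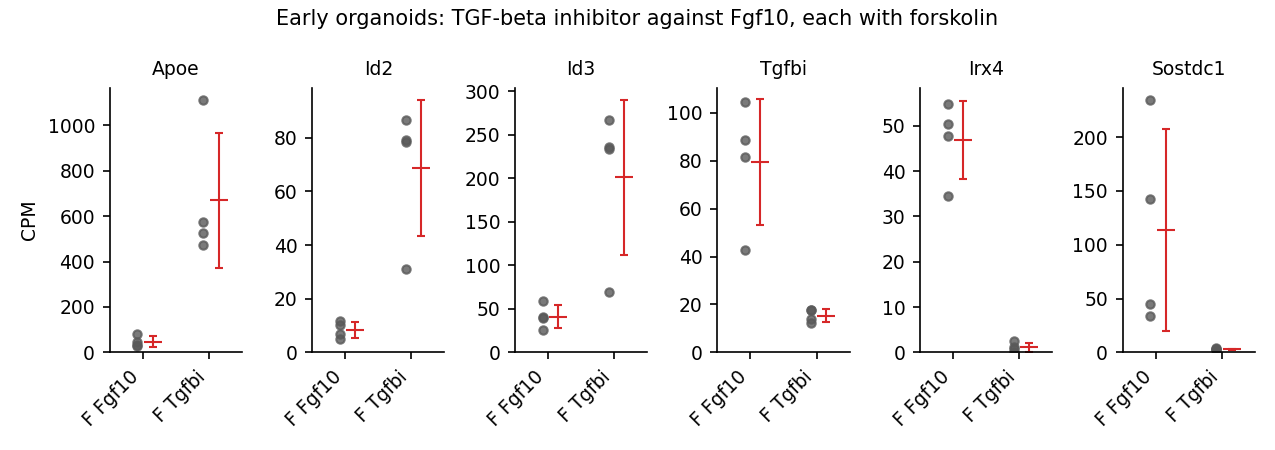
CPM of 6 genes in early organoids with forskolin and Fgf10 or forskolin and the TGF-beta inhibitor, with points for the 4 libraries of each medium and red bars for the mean ± SD. The ranges of the media do not overlap for Apoe, Id2, Id3, Tgfbi, Irx4 or Sostdc1. Lack of overlap was a condition for genes named by the size of their change, and 736 of 9919 tested genes met it.

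Forskolin was tested in early organoids by comparing the inhibitor with and without it. Genes of glucose use and hypoxia had higher averages with forskolin, with none of 20 past the test over all genes (8 rose adjusted over the list alone, median log2 fold change 1.35, adjusted p = 1.13e-11, and adjusted p = 0.300 with an estimated correlation). Targets of cyclic AMP and CREB, the pathway that forskolin activates, had a median of 1.01, with none of 17 past the test (2 rose adjusted over the list alone, adjusted p = 0.00676, and adjusted p = 0.300 with an estimated correlation). Cornified envelope genes had a median of -0.9998 over 25 genes (0 passed, also adjusted over the list alone, adjusted p = 0.589 with an estimated correlation). Lor had 1880 ± 3022 (n = 4) against 8705 ± 5187 CPM (n = 2) and Krt10 1810 ± 3015 against 6416 ± 3191, where the forskolin group's replicate 4 had a Lor level of 6135 CPM and its next highest library 424. Krt5 had 11680 ± 784 against 14280 ± 382 CPM and Krt14 11490 ± 1555 against 10950 ± 1020, and Itga6, Ly6a, Mki67 and Cd34 did not pass either. The edgeR test called 0 genes, with 623 at an unadjusted p under 0.05, and DESeq2 called 24. Without forskolin and inhibitor replicate 4 edgeR called 16.

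Early organoids were compared with unpassaged ones over the 4 media that had both, with medium as a term (12 against 4 libraries). Genes of the p53 and senescence list rose with passaging. Of 18 measured, 5 rose (9 rose and 1 fell adjusted over the list alone, median log2 fold change 0.60, adjusted p = 1.87e-05, and adjusted p = 0.0315 with an estimated correlation). Cdkn2a rose from 2.45 ± 1.01 to 24.8 ± 9.26 CPM (log2 fold change 3.37, SE 0.33, adjusted p = 2.00e-05), and the p53 targets Trp53inp1 (7.76 ± 3.45 to 25.0 ± 11.2), Ccng1 and Aen rose. Pitx1 rose from 9.55 ± 4.59 to 190 ± 110 CPM (log2 fold change 4.08) and Tubb3 from 30.3 ± 6.54 to 129 ± 23.0. Of 24 cornified envelope genes 8 rose (11 adjusted over the list alone, median 1.52, adjusted p = 0.432 with an estimated correlation), among them Lor at 4033 ± 3616 against 572 ± 699 CPM and the transglutaminase gene Tgm3. The epidermal proteases Klk14 (817 ± 644 against 30.3 ± 2.43 CPM) and Klk8 rose as well.

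B2m and H2-K1, interferon response genes and hypoxia genes were lower after passaging. B2m, a class I antigen presentation gene, fell from 901 ± 139 to 235 ± 88.8 CPM (log2 fold change -2.07, adjusted p = 8.13e-05), H2-K1 from 289 ± 45.9 to 122 ± 56.4, and 4 of 9 interferon response genes fell (5 adjusted over the list alone, median -1.02, adjusted p = 0.114 with an estimated correlation), Psmb8 from 51.5 ± 23.2 to 5.62 ± 5.78. The 3 measured genes of the Langerhans cell and class II antigen presentation list went both ways (median 0.76, adjusted p = 0.622, and adjusted p = 0.733 with an estimated correlation). Of these, named after their values were seen, H2-Ab1 fell from 34.2 ± 26.4 to 3.29 ± 7.07 CPM, H2-Eb1 rose from 1.11 ± 1.38 to 7.70 ± 6.65, and Mfge8 did not pass (2 rose and 1 fell adjusted over the list alone). Of 20 glucose and hypoxia genes 12 fell (14 adjusted over the list alone, median -0.91, adjusted p = 0.326 with an estimated correlation), including the carbonic anhydrase gene Car9 from 50.4 ± 38.7 to 3.75 ± 4.49 CPM. Of 16 basal genes 4 fell (5 adjusted over the list alone, median -0.47, adjusted p = 0.554 with an estimated correlation), among them Itga6 (chromosome 2, 71745616 to 71858416) from 273 ± 129 to 128 ± 36.7. Cd34 fell from 34.5 ± 22.9 to 4.27 ± 5.60 CPM. Targets of FGF and ERK signalling fell in 4 of 13 cases (4 adjusted over the list alone, median -0.44, adjusted p = 0.286 with an estimated correlation), Spry2 from 50.6 ± 42.4 to 10.02 ± 6.904. Krt5, Krt14, Krt10, Ly6a and Mki67 did not pass. By edgeR 1078 of 9116 genes differed, 491 higher and 587 lower. Within the source table that held the unpassaged libraries 242 genes were called, 149 of them among the 1078, and with table as a term 7, all among the 1078. Cdkn2a (3.37 within the table and 3.59 with the term), Pitx1 and Tubb3 were called in each of these fits. Of the genes that the naming rule takes, 48 lost the call within the table, a smaller fit, 36 kept their side of the threshold and 1 gained a call. For genes called in neither fit, passaging and table cannot be told apart. Without the unpassaged library with Fgf10, with Fgf1 or with the inhibitor alone, 193, 718 or 417 genes were called.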

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

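The splits of the samples, the test of genes without shared 3′ ends, the source table test of late libraries and both source table tests of passaging had predictions written before their results, while the pseudogene, dermal cell and depth tests, the test of media against passaging, the ratios on the CPM scale and the choice of the test on shared 3′ ends came after results were seen.

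Dixon's test of the highest and lowest library was made in 26 cases, on log2 CPM for genes, and 4 libraries stood apart, where chance gives about 1 in 20, or 5%. Ly6a in late replicate 4 was 86.15 CPM, with the next library at 457.4 (gap over range 0.718 on log2 CPM, and 0.469 on the CPM scale, where it did not stand apart). Cd34 in late replicate 3 was 55.61 CPM, with the next at 1.568 (0.791 on log2 CPM and 0.972 on CPM). Ly6a in early organoids with Fgf10 replicate 1 was 646.4 CPM, with the next at 1169 (0.885 and 0.848). Lor in early organoids with forskolin and the inhibitor replicate 4 was 6135 CPM, with the next at 423.7 (0.873 and 0.977). On the CPM scale the same library also stood apart in Krt10, at 6057 CPM (0.956, against 0.744 on log2 CPM). The change with passaging differed between media with and without the TGF-beta inhibitor for 3 of 9116 genes by an interaction test in edgeR, with 609 at an unadjusted p under 0.05. The 3 were Apoe (log2 difference 4.38, adjusted p = 0.009997), Tmprss2 (3.94, adjusted p = 0.009997) and Eid1 (2.75, adjusted p = 0.0393), and the contrast is partly confounded with source table. Spike-in names held at most 9 counts in a library, above the 3 counts that a count of 0 allows.

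Genes lower in anagen than in mixed follicles included many with near-identical copies. Pseudogenes or genes with a named pseudogene copy made up 73 of 588 lower genes (12.4%) and 311 of 10843 tested (2.87%), an odds ratio of 5.96 (Fisher's exact p = 9.14e-28, 95% interval 4.46 to 7.91), so reads shared with copies and counted differently in the 2 tables may account for part. Among 6496 genes that share no 31-base stretch of their 3′ end with another annotated gene, 258 (3.97%) were still lower, against 5.37% of genes with a value and 54 of 233 (23.2%) with a shared fraction of at least 0.5, which argues against copies as the whole cause. Cells of the dermis in the mixed libraries are a candidate explanation for the fibroblast genes (median -4.59), but not for Krt5 and Krt14, where the smaller change was -3.65 (adjusted p = 0.000910). The telogen follicles that the labels name stay open as an untested biological difference. Krt5 and Krt14 do not separate sheath from interfollicular epidermis, and epidermis in the mixed libraries was not tested either.

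Krt10 was near 0 in 3 of 6 late libraries. Depth was argued against: at the lowest CPM of the other 3, the low libraries would hold at least 42.5 times the Krt10 counts seen. Late libraries of the same source table differed by 0.55 in the mean log2 CPM of suprabasal genes and all pairs by 3.16, with an exact permutation p = 0.0667 over 45 arrangements, where 0.0222 is the smallest. Source table and culture therefore cannot be told apart, since each table held 1 or a pair of late libraries. No biological explanation was tested, as the labels give no difference among these libraries.

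Early and unpassaged organoids lay partly in different source tables. Of 109 genes called across tables in the inhibitor media, 77 (70.6%) had the same sign within 1 table in the Fgf media, with no shared library. The share was 52.6% among genes picked for a high unadjusted p across tables, and that of all uncalled genes was not measured. The 70.6% argues against the table as the whole cause. The glucose and hypoxia genes had a median of -0.81 within that table, lower for 18 of 20, and -0.82 across tables. Passaging itself stays open as the difference the design names, and the single unpassaged library per medium limits what the data can show.

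Other splits of the libraries into groups of the same sizes were refitted. The real split gave the most genes in 1 of 84 splits for late organoids against epidermis (2360, highest other 722) and 1 of 84 against anagen follicles (4966, highest other 895). It did so in 1 of 35 for the inhibitor against Fgf10 (57, highest other 0) and 1 of 100 drawn from 225 for passaging (1078, highest other 221). The splits take libraries as exchangeable, but late libraries share source tables and replicates may be technical, so the shares do not exclude chance. Splits that mix the real groups also raise the fitted spread, which lowers their counts. Late replicates 1 to 3 set against the other libraries gave the 722 and the 895. Late against early organoids had no such test. For epidermis against anagen follicles (3711, highest other 0) and the follicle pair (719, highest other 0) the 10 splits are too few for a share under 0.05.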

How the results depend on the processing

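Restriction to genes listed in every library, the swaps of mixed for anagen follicles and of early for late organoids, the fits without late libraries, the fits without pseudogene copies and the settings of the tissue score without single libraries were chosen after seeing the data. Of 2608 values of gene lists under other settings 2359 kept their side of the threshold without reversing. Another 223 lost the call, 22 gained it and 4 reversed. Of 11973 values of named genes these were 10786, 1127, 36 and 24. A reversal needed a call in either setting, so a change of sign with no call in both was counted as kept. With an estimated correlation 9 list tests passed in place of 86. Low counts limit genes near the filter most. Except where stated, the cause was not tested.

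Reversed here means an opposite sign with a call in either setting, so values near 0 that did not pass are included, such as Krt5 and Krt14. With mixed in place of anagen follicles, epidermis minus follicles reversed for Col6a1 (-0.50), Defb6 (-2.09), Hspa1b (-0.41), Krt14 (-0.22), Krt17 (-1.34), Krt5 (-0.12), Krt79 (-1.24), Ly6a (-0.23), Plin2 (-0.80) and the outer root sheath list (-2.18). Late organoids minus follicles reversed for Gapdh (-4.90), H2-Ab1 (-0.17), H2-Eb1 (-1.57), Hells (0.13), Mgst1 (-0.49), Mki67 (0.42), Sostdc1 (-0.95), Sparc (-1.17) and Tgfbi (-1.73), and in their tests for the fibroblast (median -4.60) and outer root sheath lists (median 0.38). With early in place of late organoids, Id2 (-1.23) and Mcm5 (0.0112) reversed against epidermis.

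Counts of genes moved by over 1.5 times as follows. The follicle pair gave 362 when thinned and 400 to 662 with single libraries left out (400 without anagen replicate 2, 439 and 458 without mixed replicates 2 and 3). Late organoids against epidermis gave 1377 in a fit of these groups alone and 1296 to 2548 with single libraries left out (1406, 1296 and 1528 without epidermis replicates 1, 2 and 3), and against anagen follicles 3305 when thinned. Late against early gave 1137 with DESeq2, 1 in a fit of these groups alone, 298 when thinned and 44 to 1097 with single libraries left out (85 and 44 without early replicates 1 and 2, 1097 without late replicate 4). A fit with fewer samples estimates the spread from fewer libraries, and a group left with 1 library was assumed to vary like the others.

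Fgf1 against Fgf10 gave 15 genes with DESeq2, 3 without a count filter, 43 in a fit of these groups alone, 4 with source table as a term, 23 without late libraries in the fit and 0 to 6 with single libraries left out (6 without Fgf10 replicate 4). The inhibitor against Fgf10 gave 138 with DESeq2, 115 without a filter, 123 in a fit of these groups alone, 8 when thinned, 103 with source table as a term, 218 without late libraries and 17 to 47 with single libraries left out (23 and 30 without Fgf10 replicates 1 and 2, 33, 21 and 17 without inhibitor replicates 1, 2 and 3). Forskolin gave 24 with DESeq2, 19 without a filter, 5 in a fit of these groups alone, 4 with genes listed in every library, 32 without late libraries and 0 to 16 with single libraries left out (16 without replicate 4 with forskolin). Passaging gave 1663 without a filter, 7 with source table as a term, 242 within the table of the unpassaged libraries and 193 to 1294 with single libraries left out (193, 718 and 417 without the unpassaged library with Fgf10, with Fgf1 or with the inhibitor alone). The tissue score difference of late minus early was 0.4225 without late replicates 1 and 2, and 0.4886 to 0.5993 with single libraries left out, where fewer arrangements raise the smallest p.

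Replicate numbers did not pair the samples: correlations of same-numbered libraries ran from -0.13 to 0.36, and in no comparison were all above 0.1. With the number as a replicate block, forskolin gave 33 genes and passaging 89. Reversed under the block were late minus epidermis for Krt10 (-6.71) and Lor (-2.46) and, in its test, the cornified envelope list (median 0.69), late minus anagen follicles for Krt10 (-2.48), and late minus early for Lor (-5.78).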

Other observations

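The genes in this part were chosen after their values were seen, and their CPM are scaled over all 32 libraries. Pitx1, a homeobox gene, had no count in the 9 tissue libraries. It had 4.75 to 14.9 CPM in the 5 unpassaged libraries, 169 ± 51.6 in early organoids with Fgf1 (SD, n = 2), 211 ± 44.1 with Fgf10 (n = 4), 233 ± 144 with forskolin and the inhibitor (n = 4) and 42.9 ± 2.75 with the inhibitor alone (n = 2), and 477 ± 274 in late organoids (n = 6). Sox2, a transcription factor of stem and dermal papilla cells, had no count in tissue, 10.1 ± 0.410 CPM in early and 95.3 ± 71.5 in late organoids with Fgf1. Apoe went the other way, from 11760 ± 2140 CPM in sorted epidermis (n = 3) through 417 to 1241 in unpassaged organoids to 31.7 ± 10.2 in early and 8.67 ± 3.59 in late organoids with Fgf1, but was 670 ± 297 with forskolin and the inhibitor and 603 ± 145 with the inhibitor alone.

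Krt15, a basal and bulge keratin, was 8033 ± 454 CPM in sorted epidermis. In unpassaged organoids it was 3.65 with forskolin, 6.88 with added Fgf10 and 7.43 with added Fgf1, against 176 with forskolin and the inhibitor and 198 with the inhibitor alone, with 1 library for each medium and no test. Krt4, a keratin of oral epithelium, averaged 6042 ± 14580 CPM in late organoids, from 0 to 35800, with the highest value in replicate 4, where it was the most abundant gene at 3.89% of counts. Wdr92 ranged from 886 to 11020 CPM over the organoid groups and was 72.6 ± 20.5 in sorted epidermis, 49.0 ± 3.12 in anagen and 144 ± 50.5 in mixed follicles.

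The unpassaged library with forskolin alone entered no comparison. It had 11140 CPM of Krt5, 19970 of Krt14, 572.8 of Itga6, 29.2 of Cd34, 265 of Krt10 and 93.1 of Krt1, a suprabasal keratin. The unpassaged library with the inhibitor alone had 3751 CPM of Krt10 and 1586 of Krt1.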
